A study of Apis mellifera with 9 samples.

How the data were processed

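Ovaries of honey bee (Apis mellifera) workers were profiled in 3 pools, each of 40 ovary pairs dissected from workers of a single colony. According to the submitters, 5 colonies with sister queens were kept, brood frames were held at 34 °C and 80% humidity, and marked workers were collected 4 days after emergence. Each pool number carries 3 kinds of library, which makes 9 libraries: an RNA-seq library for mRNA and lncRNA from rRNA-depleted RNA with a strand-specific kit, a circRNA library from rRNA-depleted RNA digested with RNase R, and a small RNA library for miRNA. The labels give 1 biological group and no treatment, so the comparisons made here are between classes of RNA, between gene lists and between pools.

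The authors gave mRNA and lncRNA levels as FPKM, fragments scaled to exonic length and library size, per gene. The circRNA values are a normalised signal computed by the authors, SRPBM (back-spliced reads scaled to mapped reads), per back-splice junction. For miRNAs the deposited tables hold a raw read count and an RPM value (reads scaled to a library total) per library, for known miRNAs and for those the authors list as newly predicted. The RPM values per the file headers divide by library totals that are larger than the listed reads, which hold 77.8%, 89.7% and 88.6% of those totals in pools 1 to 3. The submitters' processing notes name Bowtie without a version, Bowtie2 2.0.6, TopHat2 2.0.9 and HTSeq 0.6.1 without saying which step each served, and the genome build is not given in the sources used here. Chromosome positions are those of the deposited tables and the annotation used here, with linkage groups written LG. The strand rule used in counting is not stated, so levels of overlapping genes on opposite strands carry an uncertainty that could not be measured, and the same holds for near-identical copies such as the lethal(2)essential for life cluster, the takeout genes and the major royal jelly proteins.

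Depth was taken from the files. FPKM multiplied by exonic length fell on whole multiples of a single step per library for 13202 of 13204 features (99.98%, within 1e-06), which gives totals of 31930244, 27684048 and 26602582 fragments for pools 1 to 3, with 95.5%, 95.1% and 95.4% of them in listed features. These recovered fragments served for depth, lengths, a fragment minimum, the dispersion and the fragments of the miR-3759 gene in the closing section. The listed miRNA reads came to 4772099, 7277025 and 6682028. Every SRPBM value was a whole multiple of 1 step per library (tolerance 0.1 step). Whether 1 step stands for 1 read could not be checked, so the depth of the circRNA libraries is unknown here and no interval was derived from SRPBM. Shares of miRNA reads in a single library carry 95% Wilson intervals, and a count of 0 is given the share of 3 reads as its upper limit. Both cover counting error only.

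The main comparisons, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except for the 2 further list tests and the alternatives that are said to be chosen later. Features at FPKM 1 or above counted as expressed. The lncRNA level minus the mRNA level was the difference of the median log2(FPKM + 1) of features with mean FPKM above 0.1 in the same library, tested with a two-sided exact sign-flip permutation test. The 28 gene lists were matched to protein-coding features by symbol and product name (432 features after 23 name collisions were removed on the annotation alone), and the median over members of the mean log2(FPKM + 1) was set against 10000 random lists of the same size, two-sided, with Benjamini-Hochberg adjustment over lists at 0.05. Several lists were matched in part, such as 8 of 19 members for cell death, 5 of 10 for eggshell, 6 of 10 for meiotic recombination and 3 of 6 for cuticle. A list value describes the matched members alone. The SD beside a list median is that of the 3 pool medians. Features with mean FPKM of 5 or more were counted as differing between pools when the highest library was at least 2 times the lowest, without a test, since each pool is 1 library. After the data were seen, a further test was added of whether a list sat higher or lower in a pool than in the mean of the other two, for features with mean FPKM of 1 or more, against random lists matched on level (28 lists by 3 pools, 84 tests), and again against lists matched on exonic length and level. The circRNAs were matched by coordinates and strand. For circRNA against host level, Spearman's rho across host genes was tested with 100000 resamples per library. Lists were also compared, in a test added after the data were seen, for their number of circRNA hosts with random lists matched on gene span and level. Each miRNA was tested for equal shares over libraries with a chi-square test of homogeneity where every expected count was at least 5, with Benjamini-Hochberg adjustment. The biological coefficient of variation (BCV), the relative spread between pools beyond counting noise, was estimated with edgeR and TMM factors for miRNAs with at least 10 reads in each library. Same-numbered libraries of different kinds were set side by side.

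Genes were named by a fixed rule: the 15 protein-coding features and 5 lncRNAs with the highest mean FPKM, the 3 highest members and the lowest member of each list, the members vasa, nanos, vitellogenin and its receptor, Kr-h1, EcR, Notch, Egfr, Dnmt3, anarchy and buffy where matched (buffy was not), the 10 features with the highest ratio between libraries, the 15 highest circRNAs found in all pools, the 5 hosts with most circRNAs, the 15 highest miRNAs, the 5 highest newly predicted ones, and the 5 miRNAs with the largest chi-square. Not every gene the rule takes is printed. Product names are given without marks such as predicted or low quality protein and without a trailing -like. The name of a LOC feature can therefore rest on similarity alone. Other genes are said to be chosen after their values were seen.

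The alternatives covered FPKM thresholds, the pseudocount, filters on low values, junctions merged within 5 bases, other normalisations, and leaving out each pool in turn. The effect of each is given in the closing section. Groups of 3 libraries were not tested for single outlying samples, and no other grouping of the samples was tested since there is 1 group.

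The steps were tested on simulated data. With 199 simulated features holding a fragment, the length was recovered in 92.5%, and the length or a whole divisor of it in 100%. The chi-square test called 0 of 127 miRNAs with equal shares. With a 1.5-fold change in 1 library it called 29 of 30 changed miRNAs and 2 unchanged ones (127 tested), and with a 2-fold change 30 of 30 and 0 unchanged ones (125 tested). The random-list test (10271 genes, 28 lists) called 0 lists without a shift and 22 with a log2 shift of 2. The matched test of pool deviations (8601 genes, 28 lists) called 0 without a shift and 28 with a shift of 0.5. Both list simulations drew genes at random, so they do not cover lists whose genes vary together or share a length. They give no rate of false calls for the real lists. The rank correlation over 1700 genes gave p under 0.05 in 1 of 40 simulations without a correlation and in 40 of 40 with a correlation of 0.15. A simulated BCV of 0.36 over 112 miRNAs was estimated as 0.378. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.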

Results

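Ovaries of worker honey bees were measured in 3 pools, with 1 RNA-seq, 1 circRNA and 1 small RNA library per pool number. The study set out to catalogue the coding and non-coding RNAs of the worker ovary. The RNA-seq table listed 13204 genes, of which 10271 were protein-coding, 2673 lncRNAs and 170 miRNA genes, from libraries of 26602582 to 31930244 fragments. The circRNA table listed 11794 junctions, and the miRNA tables listed 152 known and 12 newly predicted miRNAs from 4772099 to 7277025 listed reads per library. Values are given as mean ± SD over the 3 pools (n = 3) unless pools are named. Where 3 values are given for 1 gene, they are pools 1, 2 and 3 in that order. Some means below 0.05 FPKM rested on a single pool.

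The most abundant protein-coding transcript was that of CSP3, a chemosensory protein of a family of small soluble proteins, at 13504 ± 7111 FPKM (n = 3). The antimicrobial peptides abaecin (LOC406144) and hymenoptaecin (LOC406142) reached 3406 ± 1045 and 1449 ± 1364 FPKM, the latter with 2990, 965 and 393 by pool and a mean of 679 without pool 1. The chaperone Hsc70-4 stood at 2066 ± 890.3 FPKM, the iron storage subunit ferritin heavy chain (LOC551684) at 1649 ± 362 and the predicted Bax inhibitor 1 (LOC552282), of a family of cell death regulators, at 1846 ± 174. The ribosomal proteins RpS24 (LOC408799) and RpS3a (LOC413296) reached 1839 ± 495 and 1415 ± 95.04 FPKM. Inositol-3-phosphate synthase (LOC551143) had the smallest SD of the 15 highest features, at 1342 ± 36.5 FPKM. Cyp4g11, a cytochrome P450, stood at 1424 ± 626 FPKM and a chymotrypsin inhibitor (LOC725380) at 1571 ± 484. The 15 highest features also held the uncharacterised genes LOC726268 (1907 ± 1236 FPKM) and LOC408421 (1339 ± 322 FPKM). A mitochondrial feature listed as protein-coding without a product name (rna29235) reached 6109 ± 3874 FPKM, and what it encodes is not given in the table. An FPKM of 1 or more was reached by 9906 ± 115 genes per pool (75.03%), among them 8531 ± 95.5 protein-coding genes (83.1%) and 1220 ± 66.0 lncRNAs (45.6%). In all 3 pools it was reached by 8221 protein-coding genes and 974 lncRNAs. Across genes, log2 levels of pools 1 and 2, 1 and 3, and 2 and 3 had Pearson correlations of 0.966, 0.975 and 0.985, with genes not independent replicates.

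The lncRNAs, long transcripts without a coding frame, sat well below the mRNAs of the same libraries. Their median log2(FPKM + 1) was 1.04 ± 0.07 against 4.08 ± 0.05 for protein-coding genes, a difference of -3.04 ± 0.07 (n = 3), which exceeded the spread between pools. The median FPKM was 1.09 for 2360 lncRNAs and 16.2 for 9817 protein-coding genes. A few lncRNAs reached the level of abundant mRNAs: LOC102653599 stood at 1738 ± 749 FPKM, Ancr-1, a non-coding nuclear RNA of the bee, at 594.7 ± 49.6, and LOC102656130 at 416 ± 247 (277 without pool 1). LOC725381 stood at 195 ± 157 FPKM (105 without pool 1) and LOC107964104 at 159 ± 80.4. The difference had the same sign in 3 of 3 pools (-3.12, -2.98 and -3.02), with an exact two-sided sign-flip p of 0.25, the smallest that 3 pools allow. Of the 2673 lncRNAs, 1534 (57.4%) overlap a protein-coding gene on either strand, and their reads are uncertain in that measure.

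Among the lists for the work of the ovary, 13 of the 21 members of the germ line and piRNA pathway list were matched, to 17 features, and the others were not matched. All 17 features had a mean FPKM of 5 or more, with a median log2 level of 4.93 ± 0.36 (n = 3) against 3.97 for all protein-coding genes. Cytoplasmic polyadenylation element-binding protein 1 (LOC411907), entered in the list as orb, led with 222 ± 96.8 FPKM, at 110.04, 280.3 and 275 by pool. The maternal protein exuperantia (LOC551582) stood at 69.8 ± 8.95 and tudor domain-containing protein 15 (LOC100576747) at 67.8 ± 0.749. The germ cell helicase vas stood at 23.4 ± 4.62, nanos, a germ cell translational repressor, at 9.24 ± 1.01 and maelstrom 2 (LOC100576828) at 5.71 ± 0.530 FPKM. The list was not past the threshold (adjusted p = 0.135). The yolk and lipoprotein uptake list was above random lists (8 features, median log2 6.004 ± 0.02, adjusted p = 0.0137), led by apolipophorins (LOC408961) at 645 ± 152 FPKM, the apolipophorin-III gene A4 at 514 ± 87.1 and clathrin heavy chain (LOC550716) at 104 ± 10.7. Vg, the yolk precursor vitellogenin, stood at 35.7 ± 8.03 FPKM and the receptor that takes it up (LOC725920) at 8.59 ± 3.01. The meiotic recombination list (6 features, median 2.90 ± 0.41, adjusted p = 0.548) held the homologous pairing protein HOP2 (LOC726449) at 16.2 ± 5.38 FPKM, MRE11 (LOC413400) at 7.89 ± 2.86 and SPO11 (LOC726963), which makes the meiotic breaks, at 0.491 ± 0.345 (0.3001 without pool 2). The cell cycle list (18 features, median 3.92 ± 0.14, adjusted p = 0.945) held topoisomerase 2 (LOC724215) at 34.2 ± 3.47 FPKM, Cdk2 (LOC409959) at 31.5 ± 2.82, Mcm5 (LOC551903) at 26.8 ± 1.38 and cyclin E (LOC411327) at 3.07 ± 0.776. In the eggshell and follicle list (5 features, median 3.09 ± 0.47, adjusted p = 0.607) the adhesion protein fasciclin-3 (LOC724243) stood at 204 ± 57.6 FPKM and C/EBP (LOC411207) at 56.7 ± 9.13. Chorion peroxidase (LOC412013), an eggshell cross-linking enzyme, stood at 0.319 ± 0.172. The cell death and autophagy list (9 features, median 5.12 ± 0.13, adjusted p = 0.176) was led by the autophagy receptor sequestosome-1 (LOC408686) at 238 ± 57.1 FPKM, followed by caspase-2 (LOC100576819) at 54.9 ± 8.01 and apoptosis-inducing factor 1 (LOC412212) at 48.2 ± 7.92, with caspase-1 (LOC100576484) lowest at 2.93 ± 0.838. The peroxisomal membrane protein PMP34 (LOC551241), entered in the lists as anarchy, stood at 26.8 ± 13.02 FPKM, with 41.7 in pool 1 against 17.4 and 21.4.

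Genes of hormone and growth pathways spanned a wide range of levels. In the insulin and TOR list (15 features, median log2 4.87 ± 0.22, adjusted p = 0.183) the translation repressor 4E-BP (LOC725039) reached 432 ± 102 FPKM, the transcription factor FoxO (LOC727091) 164 ± 21.8 and the TOR activator Rheb (LOC409036) 153 ± 9.56. Insulin-like growth factor I (LOC107964907) stood at 1.25 ± 0.389. Of the 7 members of the juvenile hormone list, 3 were matched, to 9 features. The others were not matched by symbol or product name, which does not show that they are absent from the data. The list value therefore leaves out most of the pathway. The list median was 1.33 ± 1.40, or 0.50 without pool 1 (adjusted p = 0.0849 against random lists). The list held Kr-h1, the transcription factor induced by the hormone, at 82.1 ± 26.2 FPKM, with 54.1, 106.1 and 86.2 by pool. It also held a pair of takeout genes, LOC100577380 (350.0, 17.2 and 27.4 FPKM by pool) and LOC726981 (100.5, 6.43 and 7.67 FPKM). Juvenile hormone esterase (LOC552199) stood at 0.00599 ± 0.0104 FPKM, and the direction of the list depended on its low members and on pool 1. It was below random lists without pool 1 (adjusted p = 0.0105), while with features above FPKM 0.1 alone its median lay 0.17 above the background (adjusted p = 0.844), and these are the ends of the range over alternatives. In the ecdysteroid list (16 features, median 3.39 ± 0.30, adjusted p = 0.548) Usp, the partner of the ecdysone receptor, stood at 60.3 ± 13.7 FPKM, Mblk-1 at 44.2 ± 9.70 and FTZ-F1 beta (LOC413474) at 27.1 ± 4.07. The receptor itself (Ecr) stood at 16.3 ± 3.36 and the synthesis enzyme CYP307A1 (LOC410495) at 0.188 ± 0.0962. The Notch list (15 features, median 3.38 ± 0.25, adjusted p = 0.548) was led by groucho (LOC408894) at 36.6 ± 4.85 FPKM, presenilin (LOC413169) at 35.9 ± 0.342 and mastermind (LOC408877) at 25.5 ± 6.42. The receptor Notch (LOC413289) stood at 8.36 ± 2.22 and its ligand jagged-1 (LOC411086) at 2.47 ± 0.805. The EGFR and MAP kinase list (9 features, median 4.16 ± 0.24, adjusted p = 0.856) held MAP kinase 1 (LOC409523) at 53.4 ± 3.08 FPKM, the receptor Egfr (LOC100577393) at 25.3 ± 0.559, Dsor1 (LOC409925) at 18.3 ± 3.36 and pointed P1 (LOC102656766) at 0.0990 ± 0.0440. The BMP list (7 features, median 5.37 ± 0.13, adjusted p = 0.135) held the ligand decapentaplegic (LOC727101) at 66.7 ± 5.39 FPKM, the type-1B receptor (LOC408442) at 53.5 ± 2.54, protein 60A (LOC410776) at 44.1 ± 4.00 and activin receptor type-1 (LOC725711) at 23.1 ± 1.97. In the Hippo list (7 features, median 3.72 ± 0.28, adjusted p = 0.856) merlin (LOC100576968) stood at 53.8 ± 7.82 FPKM, the kinase of Hippo type (LOC410208) at 47.9 ± 1.23, salvador (LOC552413) at 24.6 ± 0.785 and the cadherin-related tumor suppressor (LOC410009) at 0.597 ± 0.120. The DNA methylation list (5 features, median 2.75 ± 0.20, adjusted p = 0.548) held a maintenance methyltransferase (LOC726540) at 14.6 ± 0.260 FPKM, methyl-CpG-binding protein 2 (LOC408891) at 13.6 ± 1.78, the tRNA methyltransferase Dnmt2 (LOC410512) at 5.96 ± 2.11 and Dnmt3, the de novo enzyme, at 5.25 ± 1.45. The sex determination list (6 features, median 4.77 ± 0.04, adjusted p = 0.470) held Fem at 86.3 ± 13.1 FPKM, Dsx at 68.6 ± 22.5 and tra2 at 34.9 ± 1.46. A further feature with the product name protein doublesex (LOC102654158) stood at 0.0786 ± 0.109 (0.0167 without pool 1). Biogenic amine receptors, which sense octopamine, tyramine, serotonin and dopamine, were below random lists (15 features, median 1.23 ± 0.35, adjusted p = 0.0162), but not past the threshold against random lists from all features (adjusted p = 0.14). The lowest member, 5-ht7, stood at 0.0665 ± 0.0629 FPKM (0.0998 without pool 1 and 0.0372 without pool 2). The octopamine receptor beta-2R (LOC412896) stood at 13.9 ± 2.82 FPKM, TyrR at 6.38 ± 2.58 and 5-HT1 at 5.15 ± 1.29.

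Ribosomal and heat shock proteins were the highest lists, and immune and antioxidant genes were also above random lists. Cytosolic ribosomal proteins led (75 features, median log2 8.78 ± 0.30, n = 3), with the RpS24 and RpS3a named above among its highest members and an RpL7a feature (LOC727506) at 0.0282 ± 0.0489. Heat shock proteins followed (13 features, median 7.60 ± 1.21, or 6.95 without pool 1). A pair of small heat shock genes of the lethal(2)essential for life cluster stood far higher in pool 1, LOC724488 at 2177, 122 and 124 FPKM and LOC724367 at 1688, 90.02 and 101.4. Their neighbour LOC724405 was lower (16.4 ± 7.22 FPKM) but also highest in pool 1, at 24.6, 13.5 and 11.1. Immune genes (17 features, median 5.79 ± 0.23) ranged from abaecin, hymenoptaecin and Def1 (defensin 1, 891 ± 458 FPKM) down to dorsal (LOC411712) at 1.06 ± 0.504. Antioxidant enzymes (24 features, median 5.78 ± 0.35) held Tpx-4 at 918 ± 106 FPKM, Sod1 at 627 ± 275, Gtpx1 at 509 ± 58.2 and a glutathione S-transferase (LOC102656423) at 0.0118 ± 0.0204. These 4 lists shared an adjusted p of 0.00187 over random lists.

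Lists for other tissues differed from each other in level. Muscle proteins were above random lists (19 features, median log2 5.67 ± 0.48, adjusted p = 0.00187), with TpnCI at 266 ± 78.6 FPKM, TpnCIIIa at 237 ± 99.1, tropomyosin-1 (LOC408414) at 145 ± 78.9 and tropomyosin-2 (LOC413205) at 0.121 ± 0.115 (0.0662 without pool 1). Fat body and haemolymph proteins were also above (9 features, median 6.02 ± 0.14, adjusted p = 0.0133), with the iron carrier Tsf1 at 429 ± 58.4 FPKM and the storage protein Hex70c at 2.76 ± 0.534. Apolipophorins, A4 and Vg stand in this list and in the yolk list. Haemocyte proteins (7 features, median 5.42 ± 0.16, adjusted p = 0.128) held the clotting protein hemocytin (LOC411597) at 74.6 ± 7.48 FPKM and 3 peroxidasins, LOC413025 at 65.5 ± 4.41, LOC102656466 at 48.4 ± 8.25 and LOC409000 at 1.64 ± 0.875. Head gland proteins were below random lists (19 features, median 0.88 ± 0.67, adjusted p = 0.0032), with Mrjp2 at 0.00678 ± 0.0117 FPKM. The alpha-glucosidase Hbg2 stood at 754, 304.9 and 149 FPKM by pool, a major royal jelly protein 1 feature (LOC727110) at 105 ± 18.1 and Hbg3 at 18.9 ± 5.94. Gut digestive proteins were below (22 features, median 1.70 ± 0.87, or 0.90 without pool 1, adjusted p = 0.0183), led by a triacylglycerol lipase (LOC411609) at 76.3 ± 15.5 FPKM and aminopeptidase N (LOC412808) at 54.7 ± 23.1, with trypsin-1 (LOC409626) at 0.244 ± 0.378 (0.0261 without pool 1). Cuticle and trachea proteins were below (41 features, median 1.55 ± 0.67, adjusted p = 0.00187), with Cpap3-d at 413 ± 168 FPKM. In this list Apd-3 stood at 918, 21.8 and 35.7 by pool, Apd-2 at 437, 37.2 and 65.3, and the cuticular protein LOC409002 at 0.0201 ± 0.0348. Venom gland proteins (14 features, median 1.77 ± 0.11, adjusted p = 0.056) held venom protein 2 (LOC503505) at 1821 ± 165 FPKM, Melt (melittin, the main venom peptide) at 41.4 ± 16.9, an acid phosphatase (LOC726737) at 25.6 ± 6.37 and a phospholipase A2 (LOC724436) at 0.179 ± 0.271 (0.0232 without pool 2). With features above FPKM 0.1 only, this list was past the threshold (adjusted p = 0.0238, with up to 0.317 under other alternatives). Neuronal proteins (9 features, median 1.87 ± 0.19, adjusted p = 0.164) held Syt1 at 24.9 ± 3.42 FPKM, the sodium channel Para at 13.03 ± 2.22, nAChRa8 at 4.70 ± 0.0976 and the acetylcholine transporter (LOC726278) at 0.0260 ± 0.0229. Of the 28 lists, 11 were past the threshold, 7 above and 4 below, with a smallest unadjusted p of 0.0002, the smallest that 10000 random lists give. Against random lists from all features instead of protein-coding ones, the biogenic amine, gut and cuticle lists were no longer past the threshold (adjusted p = 0.14, 0.192 and 0.0722, the highest of their alternatives, with lowest values of 0.0049, 0.0024 and 0.00187).

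**Figure D1:**
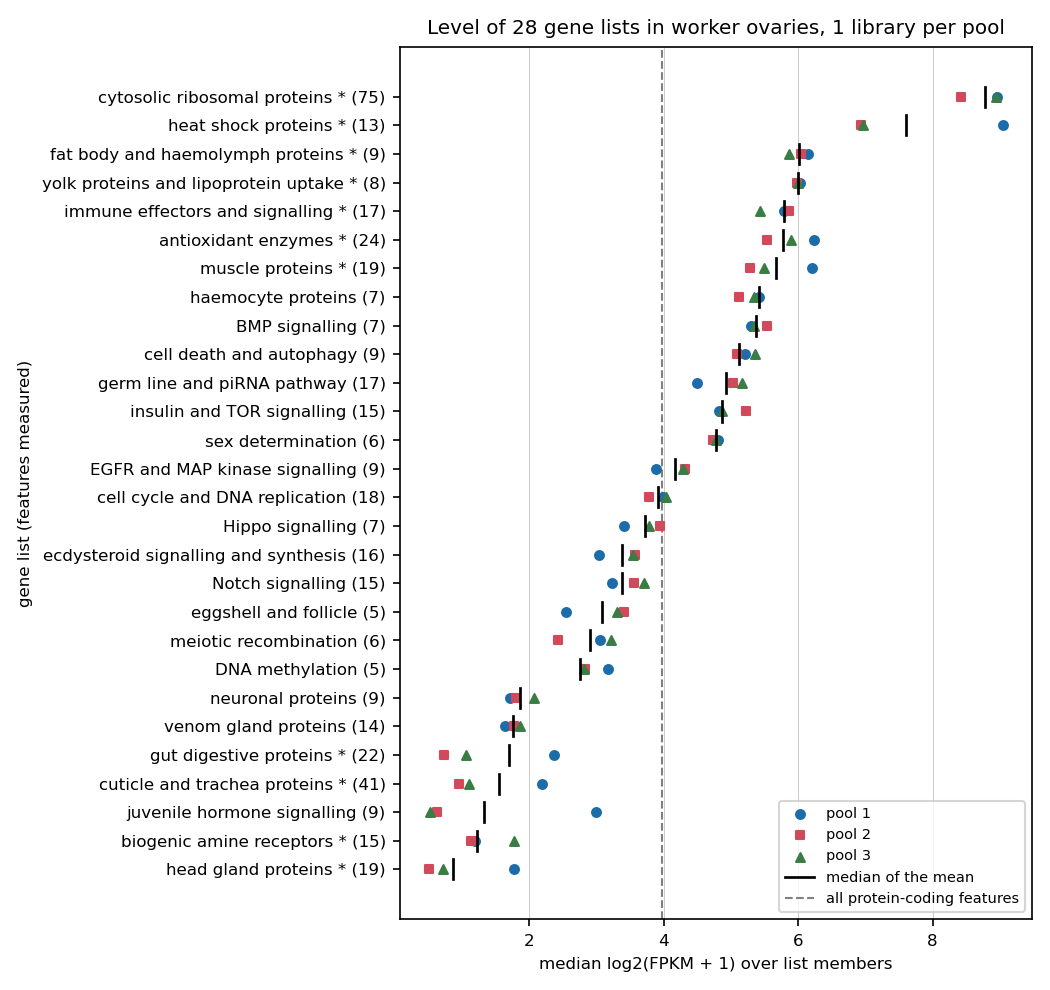
Median log2(FPKM + 1) of the members of each of the 28 gene lists, with 1 point per pool, a bar at the median of the mean over pools, a dashed line at the median of all protein-coding genes (3.97) and a star on the 11 lists past the threshold. Cytosolic ribosomal proteins lie highest (8.78) and head gland proteins lowest (0.88).

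The pools differed most in genes that stood high in pool 1. Of 7391 features with mean FPKM of 5 or more, 788 (10.7%) differed 2-fold or more between pools, of which 486 had their highest level in pool 1, 157 in pool 2 and 145 in pool 3, while 497 had their lowest in pool 2. The digestive protease chymotrypsin-1 (LOC410894) stood at 51.8, 0.0401 and 0.418 FPKM, trypsin-7 (LOC413645) at 22.1, 0.0412 and 0.515, chitotriosidase-1 (LOC100577156), of the chitinase family, at 32.7, 0.162 and 0.422, and a salivary secreted peptide (LOC100579019) at 56.9, 0.490 and 7.42. Protein G12 (LOC102654405) at 26.2, 0.0878 and 0.502, slit homolog 2 (LOC725041) at 16.9, 0.139 and 0.210, and the uncharacterised LOC724386 (73.4, 1.10 and 0.747) and LOC100577527 (44.7, 0 and 0.291) were also highest in pool 1. Membrane magnesium transporter 1 (LOC726894) at 3.78, 0.0968 and 11.7 and LOC100577341 at 9.87, 0 and 13.4 were highest in pool 3. A difference of 3-fold or more was seen in 277 features and of 10-fold or more in 58. The 788 comprised 723 protein-coding genes (10.2% of those measured) and 65 lncRNAs (20.5%). The count was 230 without pool 1, 320 without pool 2 and 680 without pool 3, and it was 1627 with features from FPKM 1. The RNA-seq BCV was 0.280 over 10917 features, and 0.193 without pool 1.

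As groups, muscle proteins were higher in pool 1 than in the mean of the other pools by a median log2 of 1.13, with 10 of 17 features 2-fold or more higher. Gut digestive proteins were higher by 0.96 (7 of 16) and heat shock proteins by 0.95 (5 of 13). Head gland proteins were higher by 0.89 (5 of 10) and cuticle and trachea proteins by 0.80 (12 of 26). The juvenile hormone list was higher by 2.51 (3 of 5) through its takeout genes. Its member Kr-h1 went the other way and was lowest in pool 1 (54.1 FPKM, against 106.1 and 86.2). Antioxidant enzymes were higher by 0.42. Ribosomal proteins (0.39), ecdysteroid genes (-0.37) and biogenic amine receptors (-0.42) were past the threshold against lists matched on level but not against lists matched on length and level (adjusted p = 0.754, 0.123 and 0.071). Fat body (0.06), venom gland (-0.11), neuronal (-0.14) and haemocyte proteins (-0.22) were not past the threshold in pool 1 (adjusted p = 0.854, 0.664, 0.692 and 0.375). In pool 2, ribosomal proteins fell by 0.73, with 26 of 74 features 2-fold or more lower, where genes matched on length and level also lay at -0.41. The other lists past the threshold in pool 2 were the juvenile hormone list (-1.80), gut (-0.69), heat shock (-0.60), muscle (-0.60), head gland (-0.57), cuticle (-0.56) and antioxidant genes (-0.49), all lower, and ecdysteroid genes, higher by 0.29. All 9 were also past it against lists matched on length and level. In pool 3, the largest shifts were those of the juvenile hormone list (-1.69), muscle (-0.71), heat shock (-0.48), cuticle (-0.39), gut (-0.39) and head gland proteins (-0.33), and smaller ones were seen for fat body proteins (-0.23), immune genes (-0.15), antioxidant enzymes (-0.15), ribosomal proteins (0.19) and yolk proteins (0.19). Each pool was set against the mean of the others, so a list high in pool 1 alone is low in pools 2 and 3 by construction, and the calls of a list in different pools are not separate findings. These groups, chosen for test after the data were seen, gave 30 of 84 past the threshold over random lists matched on level: 10 in pool 1, 9 in pool 2 and 11 in pool 3, with a smallest adjusted p of 0.000884. Matched on length as well, 27 were past it, 26 of them among the 30 and on the same side. The yolk list in pool 3 (adjusted p = 0.0533) was no longer past, and the germ line list in pool 3 (0.16, adjusted p = 0.0427) newly was. Genes of a list are not independent replicates and each pool had 1 library, so these p values describe the libraries at hand and not a difference between colonies.

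**Figure D2:**
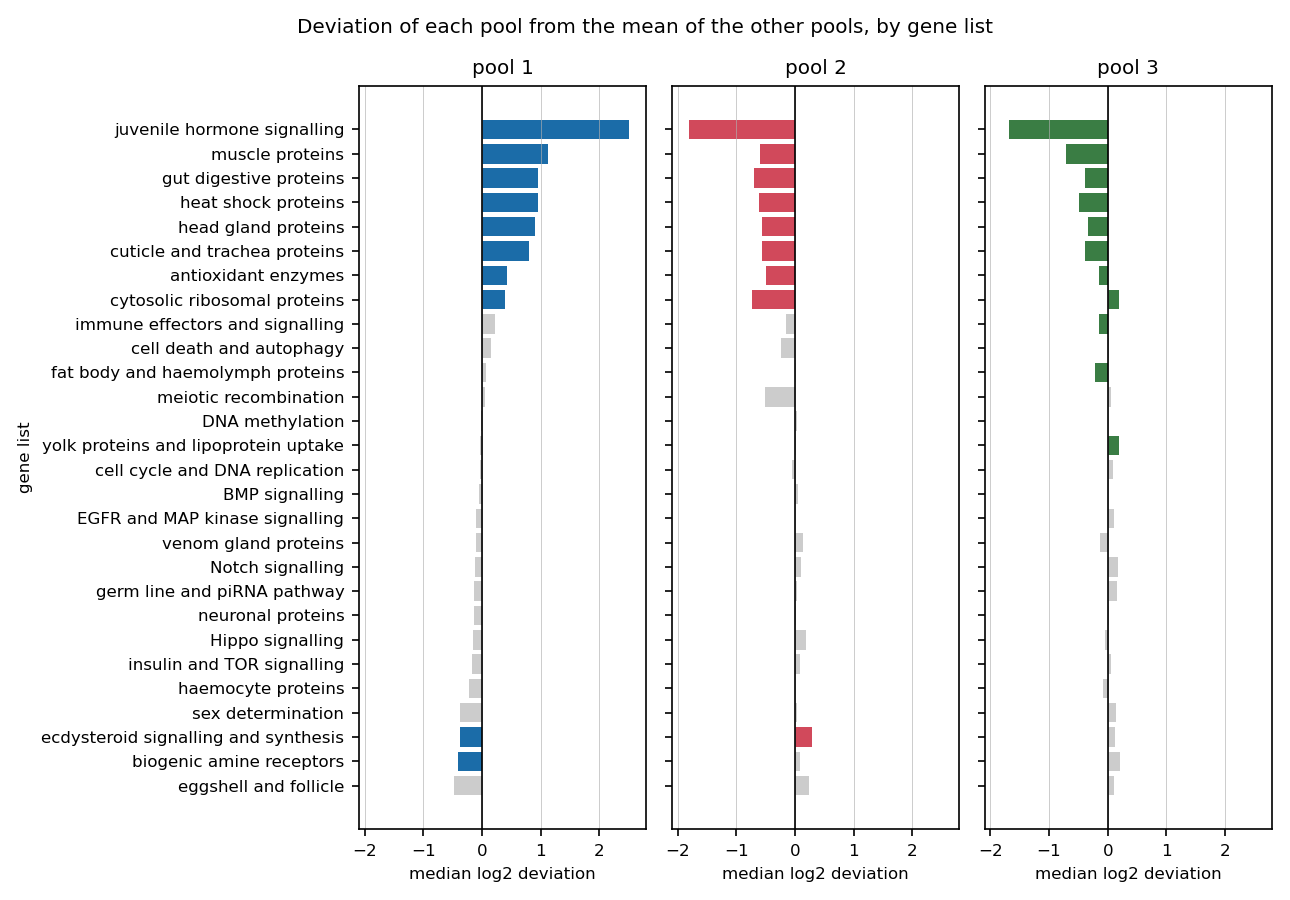
Median log2 difference of each gene list between 1 pool and the mean of the other pools, with 1 panel per pool and coloured bars for the 30 past the threshold against lists matched on level. Muscle proteins lie at 1.13 in pool 1 and ribosomal proteins at -0.73 in pool 2.

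The most abundant circRNA came from the gene of an angiotensin-converting enzyme (LOC408536), a peptidase: ame_circ_0015567 (LG15, 5368192 to 5375154, minus strand) stood at 274088 ± 11471 SRPBM (n = 3), while the host stood at 59.2 ± 7.53 FPKM. It was followed by ame_circ_0014927 of dentin matrix protein 4 (LOC410517, LG14, 7283962 to 7286062) at 159497 ± 44062 SRPBM and ame_circ_0012355 of the homeobox gene caupolican (LOC412839, LG11, 2179167 to 2180541) at 148845 ± 32615. ame_circ_0011178 of the uncharacterised LOC410006 (LG10, 3914376 to 3919784) stood at 148027 ± 20756 SRPBM, and ame_circ_0000110 (LG1, 1120280 to 1120966), listed without a gene, at 126419 ± 23661. The other ten of the highest 15 lay between 79403 and 125268 SRPBM, and their hosts include a dual cAMP and cGMP phosphodiesterase 11 (LOC410379), a calmodulin-dependent phosphodiesterase 1C (LOC724389), a heparan sulfate N-deacetylase/N-sulfotransferase (LOC413242) and zinc finger protein 395 (LOC724885). Exon structure was not used here, so the exons in each circle are not given. Pools 1 to 3 held 7009, 6373 and 8344 circRNAs. Of the 11794 listed, 3825 (32.4%) were in all 3 libraries and these carried 92.3% of the SRPBM, whereas 5687 (48.2%) were in 1 library. The median SRPBM was 1041 for the former and 217 for the latter, and the depth behind SRPBM values is uncertain, so circRNAs missing from a library are not shown to be absent.

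**Figure D3:**
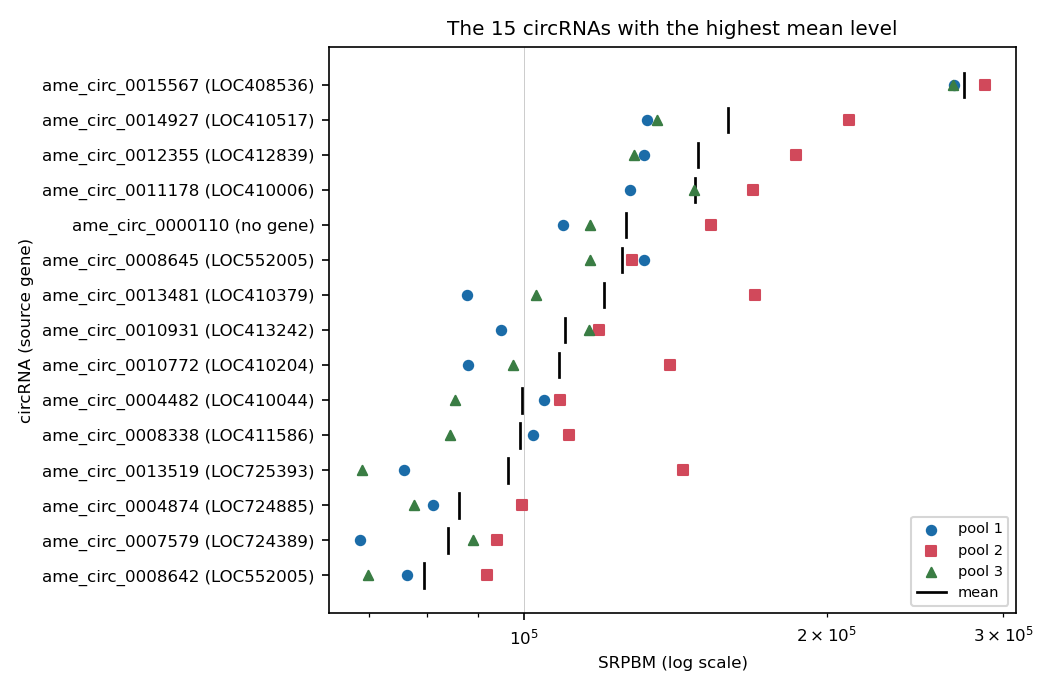
SRPBM of the 15 circRNAs with the highest mean among those found in all 3 libraries, on a log scale, with 1 point per pool and a bar at the mean. The circRNA of LOC408536 lies at 267681, 287331 and 267251, above the other 14 in each pool.

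The gene hosting most circRNAs was jazigo (LOC409786) with 58, followed by ADAMTS-like protein 1 (LOC410696) and Cac, the calcium channel subunit cacophony, with 51 each, tensin-1 (LOC408429), a focal adhesion protein, with 47 and the forkhead factor Foxp with 45. Their gene levels ranged from Cac at 4.91 ± 0.447 FPKM to tensin-1 at 117 ± 30.7 (n = 3). Altogether 2274 genes hosted circRNAs, among them 2119 protein-coding genes and 153 lncRNAs, 919 with a single one and 283 with 10 or more. Whether the level of circles follows that of the host gene was asked in each library. Host FPKM came from rRNA-depleted RNA and may include fragments of circles, so it is not a level of the linear transcript alone. Spearman's rho across host genes between summed SRPBM and host FPKM was 0.130, 0.128 and 0.155 (mean 0.137 ± 0.0150) over 1753, 1604 and 1899 hosts. The permutation p was 1e-05 in each of the 3 libraries, raw and adjusted, the smallest that 100000 resamples give, and genes are not independent replicates. All 8 measured biogenic amine receptors hosted circRNAs, against 6.51 in random lists matched on span and level, and of 18 cell cycle genes 0 did, against a mean of 1.0005. None of the 28 lists differed in hosts from the matched lists after adjustment (0 past the threshold), while heat shock proteins (4 of 13 against 1.33) and cuticle and trachea proteins (6 of 26 against 2.81) had unadjusted permutation p of 0.0438 and 0.0484, adjusted 0.678.

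The small RNA libraries were dominated by miR-276, which held 50.1 ± 6.09% of miRNA reads (n = 3), followed by miR-8 at 14.1 ± 4.39% and bantam, a growth and survival miRNA of flies, at 8.53 ± 0.632%. miR-317 held 3.51 ± 0.790%, miR-277 1.84 ± 0.492% and miR-10, encoded in the Hox cluster, 1.81 ± 0.579%. miR-9a (1.46%), miR-275 (1.40%), miR-184 (1.32%), miR-263a (1.27%, or 0.840% without pool 1), miR-279a (1.21%), miR-125 (1.11%), miR-279d (1.04%), miR-87 (0.919%) and miR-31a (0.907%) made up the rest of the 15 highest. The 10 miRNAs with the highest mean share together held 85.4 ± 2.07% of reads. Of 152 known miRNAs, 136 were in all 3 libraries. The 12 miRNAs listed as newly predicted held 0.00801 ± 0.00525% of reads (0.00501% without pool 1), with 0.0140% in pool 1 (Wilson 95% interval 0.0130 to 0.0151), 0.00573% in pool 2 (0.00521 to 0.00631) and 0.00428% in pool 3 (0.00381 to 0.00481). Among them Novel_10 had 310, 357 and 284 reads and was the 1 found in all libraries. The next highest were Novel_13 (305 reads), Novel_1 (49 reads), Novel_4 (25 reads) and Novel_8 (14 reads), each in 1 library. Novel_13 and Novel_1 were in pool 1. Their count of 0 in the other pools allows a share of up to 4.12e-05% in pool 2 and 4.49e-05% in pool 3.

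**Figure D4:**
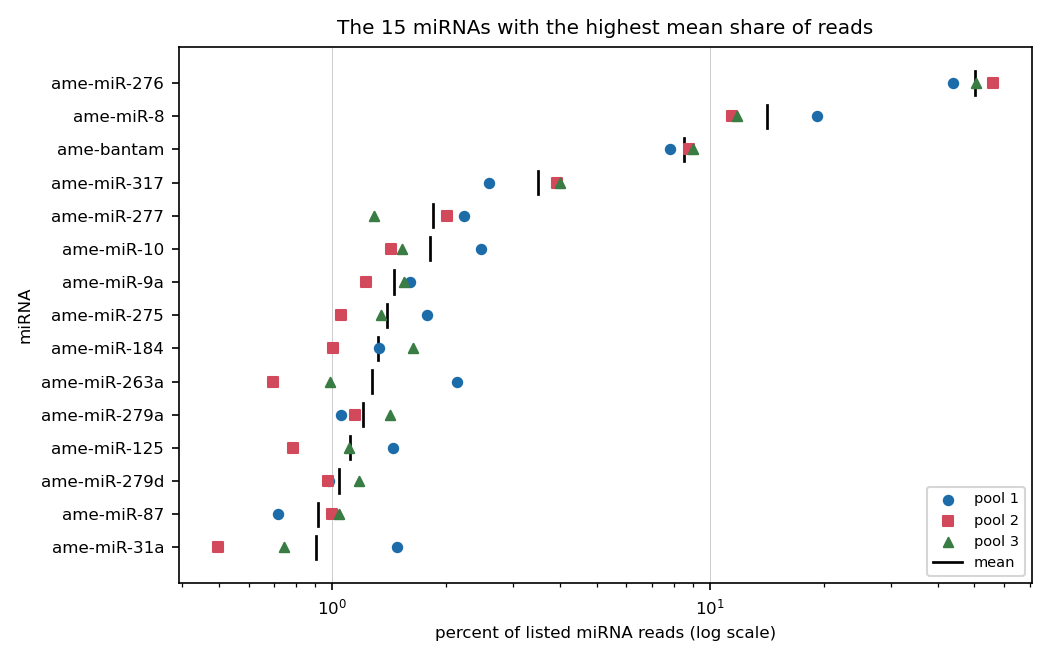
Percent of miRNA reads of the 15 most abundant miRNAs, on a log scale, with 1 point per pool and a bar at the mean. miR-276 lies between 43.9% and 56.0%, above miR-8 at 11.4% to 19.2%.

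Between pools, miR-263a and miR-31a were highest in pool 1, with highest to lowest ratios of 3.07 and 2.98, and miR-133, a muscle miRNA, was highest in pool 3 with a ratio of 3.69. miR-8 held 19.2% of reads in pool 1 against 11.4% and 11.8%, and miR-276 held 43.9% there against 56.0% and 50.5%. These 5 had the largest chi-square values, from 34764 for miR-31a to 176218 for miR-8. The let-7 complex, linked to developmental timing, held 1.94 ± 0.503% of reads (n = 3), and 3 of 3 tested members differed between libraries. Of the muscle miRNAs (0.849 ± 0.567%, or 0.528% without pool 3, where miR-133 was highest) 2 of 2 differed, miR-1 with 0.0537% in pool 1 against 0.0203% and 0.0310%. Neural miRNAs held 1.48 ± 0.201% (5 of 5 differed), nearly all of it miR-9a at 1.46%, with the next member, miR-9c, at 0.00811% and miR-124 at 0.00499%. Ovary and maternal miRNAs of flies held 10.8 ± 0.928% (6 of 7, with 7 of 8 listed members highest in pool 3), the K-box family 0.473 ± 0.0623% (3 of 3), hormone-linked miRNAs 22.2 ± 4.03% (7 of 7), the miR-279 family 3.25 ± 0.544% (5 of 5) and other broadly expressed insect miRNAs 57.5 ± 3.98% (17 of 18). Adjusted over the list alone, each of the 8 lists gave the same number of differing miRNAs. By the chi-square test with Benjamini-Hochberg adjustment, 92 of 125 tested miRNAs differed in share between libraries and 33 were not past the threshold. Every miRNA ranked above miR-92a (rank 58 by mean share) was past it, even miR-252a with a highest to lowest ratio of 1.09. The numbers called per list therefore follow read number and do not set the lists apart. The ratio of highest to lowest share was 1.63 in the median and 2 or more in 36 miRNAs, of which 18 were highest in pool 1, 7 in pool 2 and 11 in pool 3. The miRNA BCV was 0.359 over 115 miRNAs, and 0.193 without pool 1. Reads are counted without molecular identifiers, so the chi-square test covers counting noise of these libraries and not variation among colonies.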

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

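The tests of carry-over, of muscle carry-over, of scaling and both tests of the miR-3759 gene were chosen only after the result was seen, as was drawing the length-matched lists without list members; the tests of length were set before their results. For scaling, rescaling by median ratios had been set beforehand, but its factors (0.996 for pool 1 and 0.977 for pool 2) moved almost nothing. They hold much the same information as the medians over all genes below, so the rescaling is no separate test. The design holds 1 group, so no biological explanation was tested for any of these patterns, and differences between colonies stay open.

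The gene of miR-3759 (Mir3759), on an unplaced sequence at 1156 to 1247, was singled out because the RNA-seq comparisons of coding and long non-coding RNA do not use miRNA genes, and its 92 bases alone held a mean of 5.68% of all RNA-seq fragments (SD 2.82, n = 3). Its level was 617051 ± 306556 FPKM, against 2793 for Mir3732, the next miRNA gene. The library with fewest held 785675 fragments of it, which leaves no room for a few fragments made large by a short length but restates the share above rather than testing it apart. An abundant mature miRNA is argued against by the rank of ame-miR-3759 among miRNAs, 74 by mean share of reads. Reads of another abundant RNA aligned to this sequence stay open, since the sequence of the locus was not used here.

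Transcripts of several other tissues stood higher in pool 1. Carry-over of all other tissues alike was weighed with the 5 lists whose median FPKM in pools 2 and 3 was below 10. The middle 50% of pool 1 deviations ran from 0.33 to 1.51 for head gland, 0.08 to 2.09 for gut and -0.19 to 2.55 for cuticle genes. It ran from -0.43 to 0.09 for venom gland and from -0.23 to -0.04 for neuronal genes. Of the pairs of lists, 3 lay apart: neuronal below head gland and gut, and venom gland below head gland. That argues only against an equal rise of all 5 lists, and the test was chosen after these deviations were seen. Fat body and haemocyte lists, with a high level in the other pools, exclude nothing. Scaling of the whole library is argued against by the median deviation of all 8601 measured protein-coding genes in pool 1, -0.00217 with an interquartile range of 0.49, against 0.96 for the muscle, gut and cuticle lists. Transcript length is argued against by a median of 0.96 where length-matched lists spanned -0.08 to 0.18. Muscle carried over with the ovaries could not be told apart from other causes: 58.8% of muscle list members were 2-fold or more higher in pool 1 and miR-1 was highest there, but miR-133 was highest in pool 3, and muscle myosin heavy chain (LOC409843), chosen after its values were seen, stood at 72.8, 64.9 and 68.1 FPKM by pool. The values of miR-1 and miR-133 bear on this only if same numbers mark the same pools in the small RNA and RNA-seq libraries, which was not settled. Of the muscle list, 17 of 19 features had a mean FPKM of 1 or more in the ovary pools, and carry-over of single other tissues stays open.

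Cytosolic ribosomal protein transcripts were lowest in pool 2. Transcript length is argued against as the whole cause, since the median deviation was -0.73 where length-matched lists spanned -0.56 to -0.24, although matched lists were themselves lower by -0.41 in the median, which may account for part of the shift of these short transcripts (median 629 bases). Scaling of the whole library is argued against by the median deviation of all measured protein-coding genes in pool 2, -0.0651 with an interquartile range of 0.46. A length trend ran through the data: the median deviation went from 0.22 in the shortest to -0.22 in the longest genes in pool 1, and from -0.36 to 0.11 in pool 2.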

How the results depend on the processing

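The following alternatives were chosen after seeing the data: name collisions kept, random lists from all features, overlapping lncRNAs left out, other-tissue lists left out, at least 10 fragments, circRNAs inside 1 gene, and lists matched on length and level in a pool; the rest were set beforehand.

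The number of genes differing 2-fold or more between pools was 788 and became 1627 with features from FPKM 1, where more features with few fragments are tested. It ranged from 230 (without pool 1) to 680 (without pool 3) when 1 pool was left out, with fewer libraries to give a spread, and was 758 without the other-tissue lists. The miRNA BCV of 0.359 ranged from 0.193 (without pool 1) to 0.429 (without pool 3) and was 0.472 without a filter on low counts; the cause was not tested. For the main comparisons, 57 values kept their sign, their side of the threshold, or stayed within 1 SD, or within 1.5 times for a count. The other 4, those at 1627, 230, 320 and 0.193, moved further. The lncRNA minus mRNA difference was judged by its sign alone. At -3.79 and -2.57 under alternatives, it lay further than its SD of 0.07 from the main value of -3.04. Its p values, already the smallest the design allows, could not have passed the 0.05 threshold. The 57 include the share of newly predicted miRNAs, which went from 0.00801% to 0.00501% without pool 1, and the lists past the threshold, which went from 11 to 8 against random lists from all features (4 to 1 for those below). Leaving out 1 of 3 pools cannot move a mean by 1 SD. Means judged by SD with a pool left out were therefore no test of stability, though they count among the 57.

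Without the library as a block, the lncRNA minus mRNA difference stayed -3.04, with an exact permutation p of 0.1, the smallest for 3 against 3; it ranged from -3.79 (pseudocount 0.1) to -2.57 (features above FPKM 1), and was -3.11 without overlapping lncRNAs. Whether same numbers mark the same pools was checked by pairing deviations of circRNA and host levels over 1319 hosts: the correlations were 0.163, 0.0848 and -0.00408, with a one-sided exact permutation p of 0.333 (smallest 0.167), so the pairing was left open.

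Among values for lists, 185 kept direction and side of the threshold, 2 newly passed it (venom gland above FPKM 0.1 and juvenile hormone without pool 1) and 3 no longer did (biogenic amine, gut and cuticle against random lists from all features). For lists not past the threshold, 6 values of the median minus the background changed sign from below to above: juvenile hormone to 0.17 with features above FPKM 0.1, Notch to 0.00159 with name collisions kept, and, against random lists from all features with their lower background, cell cycle to 0.76, ecdysteroid to 0.23, Notch to 0.22 and Hippo to 0.56. For single genes, leaving out 1 of 3 pools cannot move a mean by 1 SD, so it is no test of stability there: of 162 named features, 32 moved over 1.5 times, 20 of them with a mean FPKM of 1 or more, and 18 of these without pool 1. The circRNAs in all pools numbered 3796 with junctions merged within 5 bases, 3798 with a higher minimum value and 3472 inside 1 gene. Of the circRNAs, 5687 were in 1 library, and with their depth unknown their absence elsewhere is not shown.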

Other observations

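The tests of gene span and of cluster mates were both set before their results were seen, while leaving out distant pairs and single clusters from the latter was chosen afterwards. Genes hosting circRNAs were long: of expressed protein-coding genes, 1.10% hosted circRNAs among the shortest span class and 75.1% among the longest, with 22.0% over all 8601. By share of measured features hosting circRNAs, biogenic amine receptors (8 of 8), neuronal (4 of 5), eggshell and follicle (3 of 4) and Notch genes (11 of 15) sat at the high end. Meiotic recombination (0 of 5), juvenile hormone (0 of 5), cell cycle (0 of 18) and ribosomal protein genes (4 of 74) sat at the low end. None of these lists differed from lists matched on span and level.

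Among mitochondrial features listed as protein-coding without a product name, rna29235 stood at 6109 ± 3874 FPKM, rna29222 at 807 ± 724 (1616, 221 and 584 by pool, and 402 without pool 1) and rna29237 at 211 ± 23.4 (n = 3); all were reported as found, and the first alone is among the 15 highest. Of 170 miRNA genes in the RNA-seq table, 116 had a value above 0 in all libraries.

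A hypothesis was that a longer gene may give more distinct circRNAs because it offers more back-splice sites. Across genes, Spearman's rho of gene span and number of circRNAs was 0.604 over 8601 genes, and 0.64, 0.58 and 0.60 within classes of low, middle and high FPKM, which is consistent with it, though genes are not independent replicates and the number of exons was not tested.

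A further hypothesis was that miRNAs of 1 cluster may keep their ratio between pools through a shared precursor. Of 15 listed pairs, 3 (miR-1 with miR-133, and miR-9c with miR-306 and miR-79) do not lie within 50000 bases on 1 strand and were left out. Over the other 12 pairs, in 6 clusters, the median SD of the log2 ratio was 0.524, at percentile 59.2 of random pairs of like read numbers (median 0.498). This lies above percentile 50, the side against the hypothesis, but only after the distant pairs were left out, a later choice. All 15 pairs, as set beforehand, gave a median of 0.480, at percentile 38.6, which met neither prediction. Over the 12 pairs the percentile ran from 6.18 to 72.7 when 1 cluster was left out. The listed pairs also missed some neighbours, such as miR-279a and miR-996 (starts 9792025 and 9791808, minus strand of the same sequence). The question therefore stays open.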
